A study of Halobacterium salinarum NRC-1 with 8 samples.

How the data were processed

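The series holds 8 two-colour arrays of Halobacterium salinarum NRC-1 RNA. Per the labels' protocols, total RNA was freed of DNA, checked for integrity and labelled with Alexa 532 or Alexa 647, and every array set a culture of the ura3 and bop knockout strain against a standard reference RNA of NRC-1 at an optical density of 0.5 to 0.6. Per the file headers, the deposited scanner tables hold for each spot the mean and median intensity, the background intensity and a confidence score, for both dyes at a high and a low scanner gain. The intensity values are not normalized and stop at 65535. The confidence score was 0 almost only for spots at that limit and was not used as a filter. Aligners, genome builds and other processing settings are not given in the sources used here.

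The authors' deposited value table holds 1 log10 ratio per spot and array. Set against the scanner values at the same slide position, it correlated with the log10 ratio of Alexa 532 over Alexa 647 of the high-gain medians at r = 0.763 to 0.985, and at r = 0.0831 to 0.320 when rows were taken in the order of the scanner table. The slopes were 0.576 to 0.933. The direction is thus the same on all 8 arrays and was turned for arrays with the culture in Alexa 647 or 532 as the labels say. The medians of the 8 columns were 0.0191 to 0.0961 on the log10 scale. How the authors normalized and centred these values is unknown, so they served as an alternative. Probe numbers were tied to spots by that position match. For 18 pairs of genes of shared complexes or pathways, the mean difference in log2 ratio was 0.11 by position and 0.28 by scanner order.

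Of the 10752 spots per array, 532 have 1 gene symbol in the platform annotation, 0 have several and 10220 have none. This gives 133 named genes with 4 spots each. All 133 symbols occur in the gene table supplied for strain 91-R6 of the species (assembly ASM479960v1), which was used for names only. No genome of the measured strain was used here, and no coordinates are given. Genes named here were fixed by a rule before the data were examined. For each comparison it took the 10 highest and 10 lowest named genes past the threshold with the same sign at both levels of the other factor, and 2 unnamed probes each way. Where fewer than 10 passed, it filled up to 10 with the largest differences of the same sign on every array difference. It added pyrF, and up to 3 members of each list by p. A named gene outside this rule (sucD and icd, for example, as members of short lists) was chosen after its values were seen.

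Medians at high gain were corrected with normexp (offset 50) and loess (span 0.3) in limma 3.58.1 under R 4.3.3. Spots at the limit in either channel took the value of the low-gain scan, where both channels lay at least 50 above background. That scan was normalized by loess on its own and shifted per array by the median difference over the brightest 10% of unsaturated spots. The 4 spots of a probe group were averaged, each array was turned to culture over reference by the dyes in the labels, and the 2 arrays of an RNA were averaged as technical replicates. The scanner tables hold no outlier marks, and no spots were left out by one. A probe group was called well above background in a channel where at least 3 of its 4 spots exceeded the background median by more than 1 background SD. Genes well above background on at most 2 arrays in either channel are given no fold, except pyrF as the knockout check, values of the low-gain scan alone, and untested differences that the closing section lists as near background. Bounds for faint genes were computed per channel after loess and Aquantile scaling.

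The main fit in limma held a mean, an oxygen term and a light term for the 4 RNA samples, with 1 residual degree of freedom and moderated variances. Tests are two-sided, with the Benjamini-Hochberg method at 0.05. The reference is a single RNA whose own spread is not measured, and differences of strain and of culture cannot be separated in that comparison. Of 16 gene lists fixed before the data were examined, 7 had at least 3 named members and were tested with camera (correlation 0.01), also with an estimated correlation and with fry. A further 7 lists were added after seeing the data. With 1 residual degree of freedom an estimated correlation is itself poorly determined. That form of camera also takes its p-value on 1 degree of freedom, so it could hardly pass any list. Not passing it therefore says little about a list.

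The steps after normalization were tested on simulated data, so background correction, loess, the joining of scans and the averaging of spots were not. The simulation held 4 RNA samples on 8 dye-flipped arrays and 2688 probe groups, with the measured dye bias and the spread of the main fit. The dye bias was the same on every array, so it cancelled in the mean of a pair, and the array noise had an assumed size. Per comparison, 100 groups were changed by 0.5 and 100 by 1. Against the reference, 91 of 100 changes of 0.5 (log2) and 100 of 100 changes of 1 were recovered. For oxygen, 0 of 100 changes of 0.5 and 74 of 100 changes of 1 were recovered, and for light 7 and 82 of 100. False calls were 15 of 206, 5 of 79 and 4 of 93. In the data the array with the culture in Alexa 532 had the larger SD of log2 ratios in every pair. In high oxygen light the SDs were 0.864 and 0.317. The simulated rates therefore need not hold for the measured arrays.

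The alternatives covered background correction, normalization, scaling, a filter on the faintest 25%, saturated spots, the authors' values, a fit of 8 arrays with a dye term and the RNA as a random block, models with only the tested factor, eBayes with trend and robust options, and leaving out each array or RNA. Added after seeing the data were the low-gain scan alone, loess within each side of the slide, spot means, saturated spots left out, 2 sets of brighter probe groups, each dye orientation alone for the agreement across genes, and camera against named genes only. Median signal over background ran from 1235.5 to 5132 units in the culture channel and from 856 to 3795 in the reference channel.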

Results

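Transcript levels were measured in Halobacterium salinarum NRC-1, an archaeon that lives in saturated brine, in a strain whose labels name knockouts of ura3 and bop. The bop gene encodes bacterio-opsin, the protein part of the light-driven proton pump bacteriorhodopsin, and the ura3 product is orotidine phosphate decarboxylase of the pyrimidine route. Cultures of 50 mL in 125 mL flasks were taken to mid-log phase in rich medium under 4 conditions that cross oxygen with light. High oxygen meant shaking at 210 rpm and low oxygen meant 100 rpm in a stoppered flask, each in light or in a darkened flask. Each condition gave 1 RNA sample, which was hybridised on 2 spotted arrays with the dyes exchanged, against a standard mid-log reference RNA of NRC-1. The 8 arrays therefore stand for 4 RNA samples, and each oxygen or light level holds 2 of them. Nothing in the labels gives a second culture of any condition, so the p-values do not measure the spread between cultures of 1 condition. The error term of the main fit is the interaction of oxygen and light, with 1 residual degree of freedom. It was moderated over genes, with 2.29 prior degrees of freedom. The SE given beside a log2 difference is the moderated one of this fit, and not the spread of the 4 RNA samples.

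Each array carried 10752 spots, which form 2688 probe groups of 4 spots. A gene symbol was given for 133 of these groups, and the other 2555 are known here only by a probe number. Between 5.16% and 10.9% of spots reached the scanner's limit at high gain. Both channels were well above background for 29.2% to 57.7% of the probe groups, depending on the array, and for 645 groups, 63 of them named, on all 8 arrays. The number of RNA samples, 4 in all and 2 per level of a factor, limits the precision.

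The first comparison checks the knockouts. The bop gene is not among the 133 named genes and was not analysed here. The gene of the ura3 product is listed as pyrF, and its log2 ratio of culture over reference was -0.25 ± 0.17 (SD, n = 4), below 0 on 5 of 8 arrays. The ratio ranged from -0.66 to 0.29 over the arrays, and it averaged 0.05 with the culture in Alexa 532 and -0.56 with the culture in Alexa 647. In limma the difference did not pass the threshold (adjusted p = 0.0875). In the reference channel pyrF was not well above background on any of the 8 arrays, at percentiles 26.1 to 38.5 of the signal, so a loss of its transcript could not have been seen. In the culture channel it was well above background on 1 of 8 arrays, high oxygen light replicate 1, where the log2 ratio was 0.29. The labels and dye directions are thus not checked by a targeted gene.

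The second comparison asks how the knockout cultures, averaged over the 4 conditions, differed from the standard reference. Of the 133 named genes 11 passed the limma test, 7 lower and 4 higher in the cultures. None of the 11 passed without high oxygen light replicate 2, without low oxygen light replicate 1 or without low oxygen dark replicate 2. The ribosomal protein gene rpl12p was lowest, at a log2 ratio of -0.76 ± 0.05 (SE, n = 4; limma adjusted p = 0.0334). The second named ribosomal protein gene, rpmC, was at -0.39 ± 0.06. Of the citrate cycle, sucC (succinyl-CoA synthetase) was at -0.47 ± 0.06 and mdh (malate dehydrogenase) at -0.34 ± 0.05. The purine synthesis genes purL and purM were at -0.47 ± 0.05 and -0.31 ± 0.05, purM being well above background on 5 arrays in the culture and 4 in the reference channel, and hemA, for the first committed enzyme of tetrapyrrole synthesis, at -0.45 ± 0.05. All 7 genes were below 0 on 8 of 8 arrays, and their adjusted p-values in limma lay between 0.0334 and 0.04997. The value of purM ranged from -0.45 to -0.08 over 28 alternatives, nearest to 0 in the authors' values, and it did not pass in 15 of them. That of mdh was -0.21 with block loess, and mdh did not pass in 13 of 28 alternatives. The calls of sucC and rpmC were lost in 10 of 29 each, of hemA in 9 of 29, of purL in 9 of 28 and of rpl12p in 7 of 29.

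**Figure D1:**
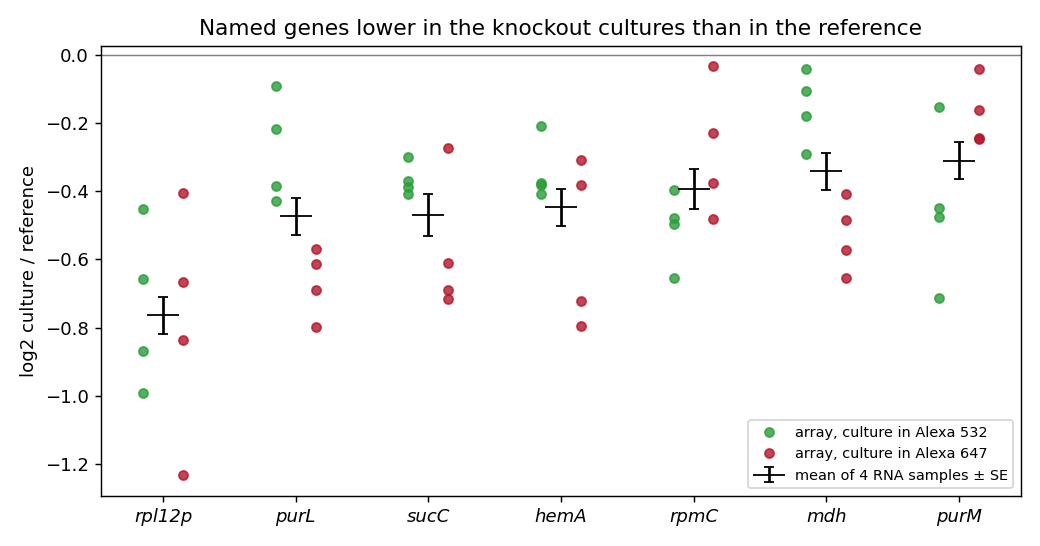
The log2 ratio of culture over reference is plotted for the 7 named genes that passed the limma test as lower than the reference. Each array is 1 point coloured by the dye of the culture, and a black mark with bars gives the mean of the 4 RNA samples ± SE. All 8 points of each gene lie below 0, and rpl12p has the lowest mean, -0.76.

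Only 4 named genes passed the threshold in the other direction, and all of them were faint. These were purB (adenylosuccinate lyase of purine synthesis), gatC (a subunit of an aminoacyl-tRNA amidotransferase), hutI (histidine breakdown) and mutL (mismatch repair). In the reference channel purB, gatC and hutI were not well above background on any array, and in the culture channel on at most 1 of 8. They were above 0 on 7, 6 and 6 of 8 arrays. No fold is given for them, since a bound set by the faintest measurable signal fell below 1. The fourth, mutL (adjusted p = 0.0456), was above 0 on 6 of 8 arrays, and with 1 array well above background in each channel it is given no fold either. All 4 genes had larger ratios with the culture in Alexa 532 than in Alexa 647. Their calls were lost in 9 of 24 alternatives for purB and for hutI, 10 of 24 for gatC and 9 of 25 for mutL.

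The gene lists fixed before the data were examined gave the following picture against the reference. Of the citrate cycle, 5 of 5 named members were below 0, with a median log2 ratio of -0.21, and 2 of them, sucC and mdh, passed the test over all genes and also when adjusted over the list alone. The other members were citZ (citrate synthase) at -0.21, sucD at -0.15 and icd (isocitrate dehydrogenase) at -0.09. The list passed camera with its preset correlation (adjusted p = 0.0291) and did not pass in 9 of its 26 alternatives, over which the adjusted p ranged from 0.000357 to 0.706. The first was an estimated correlation (adjusted p = 0.706), a test that could hardly pass any list here. The others included fry (adjusted p = 0.105), the named genes alone (adjusted p = 0.131), plain background subtraction, median centring and block loess. The rest were saturated spots left out, the groups well above background, and leaving out the array low oxygen dark replicate 2 (adjusted p = 0.0617). Both named ribosomal protein genes passed, as given above, and also when adjusted over the list alone.

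Genes for motility and taxis lay on the other side. All 9 named members were above 0, with a median of 0.12, and none passed on its own, over all genes or adjusted over the list alone. The transducer gene htr18 was well above background on 1 array in the reference channel and is given no fold. The chemotaxis genes cheR and cheA were at 0.18 and 0.14. The list did not pass camera (adjusted p = 0.340), while fry, which asks whether members move one way on balance, gave an adjusted p of 0.0400. With an estimated correlation, which could hardly pass any list here, camera gave an adjusted p of 0.706. Over its 26 alternatives the adjusted p ranged from 0.0400 to 0.706. In the authors' processed values 8 of the 9 were above 0.

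The remaining lists did not pass camera. Of the sensory rhodopsins, halorhodopsin and their transducers, 3 of 5 were above 0, with htr1 at 0.10 and sop2 (sensory rhodopsin II) at -0.04, and the list's adjusted p was 0.845. The halorhodopsin gene hop was well above background on 2 arrays in the reference channel and is given no fold. Protein folding and oxidative stress had 4 of 8 above 0, with dpsA (iron-binding DNA protection protein) at 0.21 and panB at -0.25 (list adjusted p = 0.720). For dpsA the sign turned with median centring and in the authors' values. The symbol panB is also a synonym of another gene in the reference table, so its place in this list is uncertain. DNA repair had 4 of 4 above 0, with uvrB at 0.15 and 1 member, mutL, past the threshold over all genes and adjusted over the list alone (list adjusted p = 0.467). Under block loess 3 of those 4 were above 0. Pyrimidine synthesis had 3 of 5 below 0, with carB at -0.19 and pyrI at 0.12 (list adjusted p = 0.467), and 5 of 5 with median centring and 4 of 5 in the authors' values, where pyrI was below 0 in both. Cobalamin synthesis had 3 of 4 below 0, with cbiG at -0.21 (list adjusted p = 0.340), and 4 of 4 without background subtraction, with median centring and with scaled arrays. In the authors' values it had 4 of 4 below 0 and passed camera (adjusted p = 0.0131), the only 1 of its 25 alternatives to pass, over which the adjusted p ranged from 0.0131 to 0.740.

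Lists with fewer than 3 named members were not tested. The arginine fermentation genes arcC (carbamate kinase) and arcA (arginine deiminase) were at 0.28 and 0.12, and 1 of the 2 passed when adjusted over the list alone. Over all genes neither passed in the main fit, while arcC did in 11 of 28 alternatives and arcA in 3 of 28. The respiratory chain genes sdhC and nuoL were at 0.07 and 0.02, and both were below 0 with median centring and in the authors' values. Of phosphate and metal handling, phoU, a regulator of phosphate uptake, was at -0.56 ± 0.11 (limma adjusted p = 0.0544). Its sign was not the same on all 8 arrays, and over all genes it passed in 14 of 28 alternatives. Both named members of that list passed when adjusted over the list alone. The only purple membrane gene named was bat, the bacterio-opsin activator, which was well above background on 1 of 8 arrays in each channel and is given no fold. Gas vesicles, DMSO respiration, the ATP synthase and RNA polymerase had no named member.

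Over all probe groups, 447 of 2688 passed the limma test against the reference, 321 higher and 126 lower. Of these, 233 had the same sign on all 8 arrays, and over all probe groups 512 did, or 19.0%. The arrays share the reference RNA and, in pairs, the culture RNA, so no chance level is given for these counts. Most calls were faint. The reference channel was not well above background on any array for 244 of the 321 higher and 91 of the 126 lower calls. Neither channel was on any array for 116 of the higher and 90 of the lower calls, and for 643 of all 2688 probe groups. Of the unnamed probe groups, the 2 lowest and 2 highest are given. The lowest, probe_4433 and probe_5161, were below 0 on all 8 arrays, and they were well above background in the reference channel on 5 and 3 arrays and in the culture channel on 1 and 0. The highest, probe_1953 and probe_2211, were not well above background in the reference channel on any array. None of the 4 is given a fold.

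The count against the reference depended on single arrays and on the processing. It was 0 without high oxygen light replicate 2, without low oxygen light replicate 1 or without low oxygen dark replicate 2, 115 without high oxygen dark replicate 1, and between 614 and 817 without each of the other arrays, namely 614 (high oxygen dark replicate 2), 678 (low oxygen light replicate 2), 736 (low oxygen dark replicate 1) and 817 (high oxygen light replicate 1). The split was 658 higher and 517 lower without background subtraction, 523 and 370 with median centring, and 138 and 92 with loess within print blocks. Of the 447 calls, 38 lay among the 645 probe groups well above background on all arrays, 28 higher and 10 lower. A separate fit to those 645 groups alone, chosen after seeing the data, gave 348 calls, 175 higher and 173 lower, of which 38 were shared with the 447.

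The third comparison asks what low oxygen changed relative to high oxygen, with light as an additive term. No probe group passed the limma test (lowest adjusted p = 0.680), and 174 had an unadjusted p under 0.05 where chance gives 134.4. The fit of 8 arrays with a dye term gave 0 as well. Among named genes with the same sign in every array difference and well above background on more than 2 arrays, the highest value belonged to phoU, at 0.58 ± 0.23 (SE, n = 4; adjusted p = 0.680). Next came gdhA1 (glutamate dehydrogenase) at 0.44 ± 0.11, rpl12p at 0.35 ± 0.11, serB (phosphoserine phosphatase) at 0.33 ± 0.11, infB (translation initiation factor) at 0.32 ± 0.13, purF (the first enzyme of purine synthesis) at 0.29 ± 0.11 and panB at 0.28 ± 0.14. None of these passed. The value of phoU rested mainly on the dark pair, at 0.21 in light and 0.95 in the dark. Likewise infB was at 0.19 and 0.44, and panB at 0.11 and 0.45. The other genes were closer in light and in the dark, with gdhA1 at 0.40 and 0.47, rpl12p at 0.40 and 0.30, serB at 0.37 and 0.29, and purF at 0.25 and 0.32. Over the alternatives phoU ranged from 0.20 to 0.79, rpl12p from 0.19 (without the low oxygen light RNA) to 0.73, gdhA1 from 0.32 to 0.51, serB from 0.21 to 0.46, infB from 0.05 to 0.42, purF from 0.17 to 0.39 and panB from 0.14 to 0.45. The rule also named hisD, gyrB and htr4, which were well above background on at most 2 of 8 arrays and are given no fold. Their values are left out of that order. In total 29 named genes had the same sign in all 4 array differences, 22 higher and 7 lower in low oxygen. Over all probe groups 549 did, or 20.4%. The 2 differences in light come from the same pair of RNA samples, as do the 2 in the dark, so no chance level is given.

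**Figure D2:**
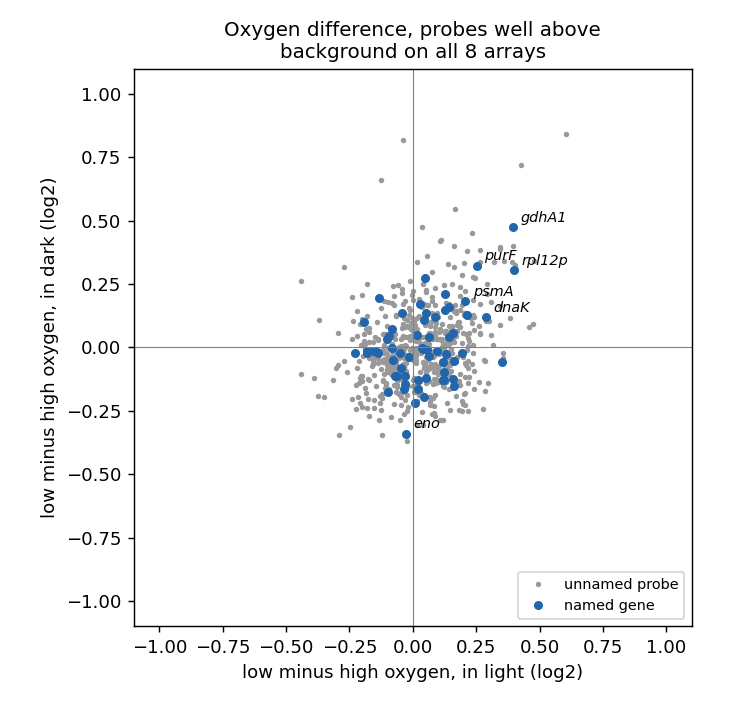
The difference between low and high oxygen in light (x axis, log2) is plotted against that in the dark (y axis, log2) for the 645 probe groups well above background on all 8 arrays, with named genes in blue. Across these probe groups r is 0.311, and gdhA1 lies at 0.40 in light and 0.47 in the dark.

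None of the 7 tested lists passed camera for oxygen with its preset correlation, nor fry for a move in one direction. With an estimated correlation none passed either, but that test could hardly pass any list. The closest was DNA repair, with 4 of 4 members below 0 and a median of -0.15 (adjusted p = 0.377). In fry's test for change in either direction DNA repair had an adjusted p of 0.0483. Its members mutL, radB and uvrA were well above background on 1 of 8 arrays each. The citrate cycle had 5 of 5 above 0 with a median of 0.10, led by sucC at 0.16 and citZ at 0.14 (adjusted p = 0.743). Under loess within print blocks 3 of the 5 were above 0, and 4 of 5 without background subtraction. Protein folding and oxidative stress had 6 of 8 above 0, with psmA (proteasome subunit) at 0.20, dnaK at 0.20 and dpsA at -0.13 (adjusted p = 0.897), and 3 of 8 in the authors' values. Motility had 4 of 9 above 0, with cheY at 0.11 and cheB at -0.10 (adjusted p = 0.897), and 5 of 9 with median centring. The retinal proteins and transducers had 4 of 5 below 0, with sop1 (sensory rhodopsin I) at -0.10, its transducer htr1 at -0.11 and htr2 at -0.07 (adjusted p = 0.743), and from 3 of 5 with median centring, block loess and in the authors' values to 5 of 5 with scaled arrays. Pyrimidine synthesis had 2 of 5 above 0, with pyrB at 0.10, and cobalamin synthesis 3 of 4, with cbiT at 0.15 (adjusted p = 0.897 for both). Of the pyrimidine genes 3 of 5 were above 0 without background subtraction, with median centring, with scaled arrays and in the authors' values. The arginine fermentation genes arcC and arcA were at -0.02 and -0.00, and sdhC and nuoL of the respiratory chain at 0.09 and 0.01. No member of any fixed list passed when adjusted over the list alone.

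The oxygen differences found in light and in the dark come from 4 separate RNA samples. Across all 2688 probe groups they correlated at r = -0.0206 (rho = 0.112), with the same sign in 56.1%, and across the 133 named genes at r = -0.0756. Across the 645 probe groups well above background they correlated at r = 0.311 (rho = 0.253), with the same sign in 58.0%. Genes are not independent replicates, so no p is given. In that brighter set, chosen after seeing the data, 19 probe groups passed limma for oxygen, 18 higher and 1 lower in low oxygen. That fit gave every group the same SE, 0.09, pooled over groups, so its p-values do not rest on the spread of each gene between the 4 RNA samples. The 2 named genes among them were gdhA1 (adjusted p = 0.000639) and rpl12p (adjusted p = 0.00818). Over 29 alternatives the adjusted p ranged from 0.000639 to 0.9998 for gdhA1 and from 0.00818 to 0.9998 for rpl12p. The low-gain scan alone, also chosen after seeing the data, gave 31 calls among 1131 probe groups, 22 higher and 9 lower, of which 4 were among the 19. Its 5 named calls were phoU at 0.73, gdhA1 at 0.51 and panB at 0.45, and thiL (thiamine synthesis) at -0.52 and glmS (amino sugar synthesis) at -0.60. For glmS the value with both scans joined had the opposite sign.

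The fourth comparison asks what light changed relative to the dark, with oxygen as an additive term. No probe group passed the limma test (lowest adjusted p = 0.892), and 117 had an unadjusted p under 0.05 where chance gives 134.4. The named genes with the same sign in every array difference had small values. Among those well above background on more than 2 arrays, the highest were cbiT of cobalamin synthesis at 0.28 ± 0.15 (SE, n = 4) and carB (carbamoyl-phosphate synthase) at 0.24 ± 0.13. The lowest were gdhA2, a second glutamate dehydrogenase, at -0.25 ± 0.11, thiD of thiamine synthesis at -0.21 ± 0.12, arcC at -0.21 ± 0.11, htr1 at -0.18 ± 0.12 and tpiA (triosephosphate isomerase) at -0.18 ± 0.11. The lowest adjusted p of a named gene was 0.999. Over the alternatives gdhA2 ranged from -0.51 without high oxygen light replicate 2 to 0.01 without high oxygen light replicate 1, arcC from -0.37 to -0.05 and cbiT from 0.10 to 0.47. Of these genes gdhA2 was well above background on 5 arrays in the culture and 3 in the reference channel, and tpiA on 8 and 4. The rule also named hisF, pyrF and thiL, which were well above background on at most 2 of 8 arrays and are left out of that order. In all, 16 named genes and 331 probe groups (12.3%) had the same sign in all 4 array differences, which share RNA samples in the same way.

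No list passed camera for light with its preset correlation, nor fry in either of its tests. With an estimated correlation none passed either, but that test could hardly pass any list. Pyrimidine synthesis had 4 of 5 members above 0 with a median of 0.18, among them carB at 0.24 and carA at 0.18 (adjusted p = 0.407). With median centring and in the authors' values 3 of the 5 were above 0. Cobalamin synthesis had 4 of 4 above 0 with a median of 0.10 (adjusted p = 0.407), and 1 of 4 with median centring and 2 of 4 with block loess. The retinal proteins and their transducers had 3 of 5 below 0 with a median of -0.16, with htr2 at -0.16 and sop2 at 0.10 (adjusted p = 0.407). With median centring and in the authors' values 5 of 5 were below 0, with medians of -0.07 and -0.03. Protein folding and oxidative stress had 4 of 8 below 0, with psmB at -0.12 (adjusted p = 0.407), and 2 of 8 in the authors' values. Motility had 5 of 9 below 0, with cheA at -0.05 (adjusted p = 0.407), and 4 of 9 with scaled arrays. DNA repair had 2 of 4 below 0 (adjusted p = 0.500), and 0 of 4 in the authors' values. The citrate cycle had 3 of 5 below 0, with sucC at -0.09 (adjusted p = 0.503), and from 2 of 5 without background subtraction and in the authors' values to 5 of 5 with median centring. Both arginine fermentation genes were below 0, at -0.21 and -0.11, and both ribosomal protein genes above 0, at 0.27 for rpl12p and 0.05 for rpmC. No member of any fixed list passed when adjusted over the list alone. Light differences at high and at low oxygen correlated at r = -0.0256 across all probe groups, at r = -0.339 across named genes and at r = 0.00138 across the 645 brighter groups. Without low oxygen dark replicate 1, 50 probe groups passed for light, and the correlation across all probe groups was 0.479.

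**Figure D3:**
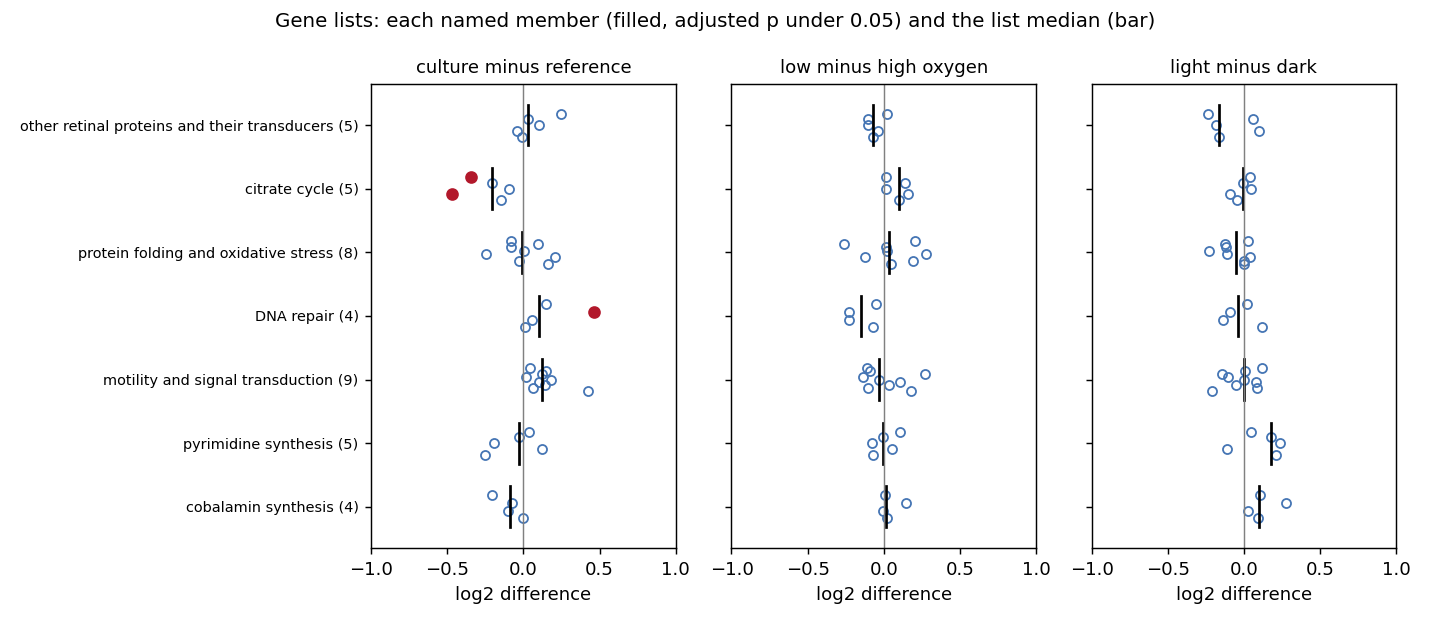
The log2 difference of each named member is plotted for the 7 tested lists (number of members in brackets) in the 3 comparisons, filled where the adjusted p was under 0.05, with the list's median as a black bar. The filled points are sucC, mdh and mutL against the reference, of which mutL was well above background on 1 array in each channel, and no member passed for oxygen or light.

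The interaction, the oxygen difference in light minus that in the dark, has no spread to test against, since each condition holds 1 RNA sample. Its SD across all probe groups was 0.47, and 0.18 across the 645 brighter groups. For 19 of 133 named genes both array differences in light had the opposite sign to both in the dark. Over all 2688 probe groups, 319 did.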

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

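All the tests of explanations in this part were chosen after the results were seen.

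For 19 of 133 named genes the oxygen difference had one sign on both array pairs in light and the opposite sign on both in the dark. Over all 2688 probe groups, 319 did. Whether this share differs between named genes and the rest was not tested, so the count does not set the named genes apart. The difference between light and dark was not tested, and since both array pairs of a light level share their RNA samples no chance level is given. In light minus in dark, the difference among genes well above background on at least 7 arrays was 0.34 for cmk, -0.33 for speB, -0.29 for argH, 0.25 for carA, 0.25 for arcA, 0.21 for pyrI, 0.17 for ileS, 0.16 for secY and -0.15 for cbiQ. The other 10 genes were well above background on at most 2 of 8 arrays, so their values come from signal near background and measure no fold: 0.71 for aroC, -0.43 for cca, 0.73 for hutG, -0.99 for hutU, 0.40 for nadA, 0.85 for nadC, -0.36 for pyrF, 0.83 for serS, -1.12 for trpB and -1.07 for trpC.

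The 2 arrays of an RNA correlated little across all probe groups, at r = -4.6e-05 to 0.139 in culture over reference. That the dyes were left unexchanged on 1 array of each pair is argued against, because arrays of opposite orientation correlated at most at r = 0.0925 when all were read as Alexa 647 over Alexa 532, while arrays of the same orientation correlated at 0.575 or more; an exchange of the dye labels on all 8 arrays would not show here. Over the 645 brighter groups the lowest correlation of the pairs was 0.308. That rise cannot tell noise near background from dye bias, since the dye component was smaller there too. A dye bias that differs between probes may account for part of the low correlation. The dye component of the covariance was 0.913 of the culture component over all groups and 0.355 over the brighter ones. In the 643 groups not well above background on any array, culture and dye components were 0.215 and 0.187 of an array variance of 0.609. In the brighter groups they were 0.0339 and 0.012 of 0.0637. A part for noise near background stays open. No biological explanation was tested.

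The oxygen differences in light and in the dark correlated at r = 0.311 among the brighter groups and at r = -0.0206 over all groups. By sign the 2 sets lay closer, with the same sign in 58.0% of the brighter groups and 56.1% of all groups. By rank, rho was 0.253 and 0.112. No single array carries the correlation among the brighter groups: with each array left out the lowest r was 0.183. The low-gain scan alone gave r = 0.264 over the 1131 probe groups measured on it, so a correlation was also found without the high-gain scan. That set differs from the 645 groups, for which the low-gain value was not computed. The low-gain values had background subtracted too, so background correction stays open. A difference in growth stage between shaken and stoppered cultures may contribute and stays open, because only 2 ribosomal protein genes are named (mean 0.199) and each condition is a single culture. The oxygen supply itself, which the design names, stays open too.

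Calls against the reference leaned towards higher, at 71.8%. Of the higher calls, 20.9% had opposite signs in the dye orientations. That share cannot decide on a signal in a single dye, because calls were chosen by their mean over both orientations, which favours equal signs. A contribution of dye stays open: 67 of 321 higher and 0 of 126 lower calls had opposite signs, and the median of the higher calls was 0.77 with the culture in Alexa 532 and 0.41 in Alexa 647. Background correction of faint spots stays open: of the 38 calls well above background on all arrays 73.7% were higher (95% Wilson interval 58.0% to 85.0%, counting error only), while a separate fit to such groups gave 50.3% and leaving out background subtraction gave 56%. No biological explanation was tested.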

How the results depend on the processing

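The labels give no replicate numbers, and those used here follow the dye of the culture, 1 for Alexa 532 and 2 for Alexa 647. Array differences were formed within a dye orientation by these numbers. The fit itself compares oxygen within light levels and light within oxygen levels. The count of 447 against the reference was 1175 without background subtraction, 0 with plain subtraction, 893 with median centring, 230 with block loess, 944 with arrays scaled to equal spread, 0 in the authors' values, 1464 with 8 arrays and a dye term, 948 with only a mean in the model, and 1117 with trend and robust options. Among alternatives chosen after seeing the data it was 0 with loess within each side of the slide, 0 with spot means and 103 with saturated spots left out. The fit of 8 arrays used a correlation of -0.227 between the 2 arrays of an RNA. A negative value makes the SE of their mean smaller than for independent arrays, which raises the count of 1464. Of the 447 groups, 405 also passed without background subtraction, 399 with median centring, 164 with block loess and 447 with scaled arrays. Without 1 array the count ranged from 0 to 817, and without 1 RNA and with only a mean in the model from 149 to 625. Leaving out an array leaves its RNA with a single dye, so probe-specific dye bias enters the mean. The 7 lower named genes stayed below 0 in every alternative run; rpl12p passed in 22 of 29 and purM no longer passed in 15 of 28. For oxygen the count of 0 became 3 without background subtraction and 1 with median centring, and, chosen after seeing the data, 31 on the low-gain scan alone, 19 among groups well above background and 26 among groups measured at low gain. The prior degrees of freedom were 2.29 in the fit to all groups and 22.1 on the low-gain scan alone, and in the fit to groups well above background the spread was pooled fully over groups. For light it became 1 with median centring and 4 on the low-gain scan alone; without 1 array the count ranged from 0 to 0 for oxygen and from 0 to 50 for light. Lists past the threshold against the reference numbered 1, and 0 with plain subtraction, median centring, block loess, an estimated correlation, named genes only, saturated spots left out or groups well above background; it was 2 in the authors' values (citrate cycle and cobalamin synthesis), and 0 to 1 without 1 array. For oxygen and light it was 0 in each alternative run with camera or with fry for a move in one direction; fry for change in either direction gave DNA repair for oxygen (adjusted p = 0.0483). The agreement of oxygen differences was 0.264 with the culture in Alexa 647 alone and -0.259 in Alexa 532 alone, -0.247 with block loess, 0.264 on the low-gain scan, 0.311 and 0.298 in the 2 brighter sets, and -0.322 to 0.395 without 1 array; that of light differences was -0.427 in the authors' values and -0.504 to 0.479 without 1 array. The SD of the interaction was 0.85 with the culture in Alexa 532 alone. For pyrF the log2 ratio was -0.51 with plain subtraction, 0.0236 in the authors' values and -0.34 to -0.17 without 1 array. Keeping spots marked as outliers was not run, since the scanner tables mark none. The cause was not tested for any of these moves unless a reason is given beside it. Signal over background limits these results too: both channels were well above it on all arrays for 645 of 2688 groups.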

Other observations

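The 7 lists described here were put together after the values were seen, so their tests are not independent evidence. Camera with an estimated correlation could hardly pass any of them, so not passing it says little. Against the reference, the 3 named genes of histidine breakdown were above 0 and were faint, with hutG and hutU well above background on at most 1 of 8 arrays like hutI. Against the named genes alone the list passed camera (adjusted p = 0.000131), and it did not pass against all probe groups (adjusted p = 0.0984) or with an estimated correlation (adjusted p = 0.406). Thiamine synthesis had 3 of 3 members below 0, with thiC at -0.17 and thiD at -0.20 (adjusted p = 0.0920, and adjusted p = 0.406 with an estimated correlation). Of 12 aminoacyl-tRNA synthetase genes 10 were below 0, with a median of -0.10, lysS lowest at -0.25 and thrS at -0.13 (adjusted p = 0.0920). With median centring 8 of the 12 were below 0. Glutamate and glutamine enzymes had 3 of 4 below 0, gdhA2 at -0.32 and gdhA1 at -0.27 among them (adjusted p = 0.0984). Histidine synthesis had 5 of 6 below 0 and protein export 3 of 3 (adjusted p = 0.117 and 0.183); with median centring these were 3 of 6 and 2 of 3.

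In low against high oxygen, 7 of 7 purine synthesis genes were above 0, with a median of 0.16 (camera adjusted p = 0.228). Among them purF was at 0.29, purM at 0.22, purL at 0.16 and purD at 0.15. Of the others, guaB and purE were near 0, at 0.02 and 0.03, and below 0 in the dark. The gene purB was well above background on 1 array in the culture and 0 in the reference channel, and was below 0 in light. With loess within print blocks 5 of the 7 were above 0, and 6 of 7 with scaled arrays and in the authors' values. The same purL and purM were below the reference in the mean of all cultures. For the other added lists, medians for oxygen ran from -0.10 for thiamine synthesis to 0.11 for glutamate and glutamine enzymes, and for light from -0.12 for histidine synthesis to 0.05 for histidine breakdown. None passed camera for oxygen or light. By fry for a move in one direction, thiamine synthesis (adjusted p = 0.0290) and the glutamate and glutamine enzymes (adjusted p = 0.0489) passed against the reference, and with camera at an estimated correlation neither did (adjusted p = 0.406 for both). By fry for change in either direction, 5 of the 7 passed against the reference, with adjusted p from 0.0141 to 0.0396, and the glutamate and glutamine enzymes passed for oxygen (adjusted p = 0.0174). With camera at an estimated correlation those 5 had an adjusted p = 0.406 and the glutamate and glutamine enzymes for oxygen an adjusted p = 0.747.

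The brighter probe group with the largest oxygen difference, probe_3453, was at 0.72, with 0.60 in light and 0.84 in the dark, and is unnamed.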
